A study of Mus musculus with 6 samples.

How the data were processed

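RNA of bone marrow stromal cells from 3 aged and 3 young mice was measured on Agilent miRNA arrays of 1 colour (Cy3), 1 array per sample. Per the labels' protocols, the RNA was extracted with mirVana reagents, and the design text counts 3 aged and 3 young mice, so the samples were taken as separate animals. Each array had 52044 spots, of which 49880 were not controls. Each of 1247 miRNAs had 1 to 4 probes and 40 spots.

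Per the file headers, the deposited intensity values were background-subtracted and spatially detrended per spot, with no normalization between arrays. The submitters' processing notes name Agilent Feature Extraction 10.7.1.1. The other deposited intensities are, per the file headers, the mean and local background signals and the totals per probe and per miRNA. The log2 values of the series' deposited matrix had column medians of -3.30, -3.32 and -3.31 in aged and -3.03, -3.05 and -3.06 in young samples. These equal the columns' minima, at which 873 to 972 miRNAs stood. Their log2 scale was found by setting them against the scanner values, and how the authors normalized or centred them between arrays is not given in the sources used here. The authors' deposited table gave probe sequences and chromosomes, with no genome build given in the sources used here. Its 18 columns of values per array were not used, since their names do not match the samples' labels.

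Signals of a probe's spots were averaged without spots marked as outliers and summed over the probes of a miRNA. Each array was divided by its 75th percentile over the 221 miRNAs detected on all 6 arrays, floored at the lowest scaled signal of any detected miRNA (0.0099, or -6.66 on the log2 scale), and log2 was taken. The 75th percentile before scaling was 667, 666 and 651 in aged and 558, 633 and 592 in young samples. A miRNA was tested when it was detected on all 3 arrays of at least 1 group. The test was lmFit and eBayes of limma 3.58.1 in R 4.3.3, aged minus young, two-sided, with 10.98 degrees of freedom and a threshold of 0.05 on the Benjamini-Hochberg adjusted p. SEs of miRNA changes are the moderated SEs of this fit. Like its degrees of freedom, they draw on the spread of all tested miRNAs, some of which stood at the floor with an SD of 0. SEs of control probes come from their own SDs. Detection is the software's call per miRNA. For a miRNA undetected on every array of a group, "at least" folds set the other group's mean against the mean of, per array, the higher of the lowest detected signal and the miRNA's own signal. Values at the floor have no order among them.

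No array was taken for a copy of another, since pairs within a group differed by more than the noise between spots (chi-square per miRNA 55.6 to 201). Any separate hybridisations would, so that the samples being separate animals rests on the design text alone. The miRNAs named were chosen by a rule fixed before the data were examined: both arms of miR-188, the 12 largest rises and 12 largest falls in fitted log2 change past the threshold, the 5 brightest, and up to 4 members of each list, those past the threshold first by fold. The remaining members of the miR-188 cluster and the undetected members and exceptions in lists were named after their values were seen. So were arms and let-7 members outside the lists, miR-6368, miR-3096b-5p and miR-3473c.

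The lists, also fixed before the data were examined, were the miR-188 cluster, miRNAs that target Runx2, pro-osteogenic, pro-adipogenic, anti-adipogenic and senescence miRNAs, the let-7, miR-17, miR-29 with miR-30, and miR-466 to miR-297 families, markers of mesenchymal, leukocyte, erythroid, endothelial, epithelial and muscle cells, the Dlk1-Dio3 region, and GC-rich miRNAs. Of these 18 lists, 16 had at least 3 tested members and were tested with camera at a correlation of 0.01, with an estimated correlation, and with fry. Members of near-identical families share signal and are uncertain one by one.

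On simulated arrays with the 393 tested miRNAs, 20 runs and 100 changed miRNAs, the aged against young fit called 59.3% of changes of 0.5 and 93.6% of changes of 1 on the log2 scale, and 0.939% of unchanged miRNAs. A simulated fall of 0.5 in the mesenchymal list was found in 20 of 20 runs, with 2 of 180 unrelated lists called. The simulated miRNAs varied independently of one another, so these runs do not show how often camera calls lists of correlated miRNAs.

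Alternatives fixed before the data were examined changed the background correction, scaling, summary over probes, filter, floor, test, source of values, blocks and replicates. Those added afterwards scaled arrays to 4 dmr or to 5 hur and mr control probes, summed the totals of probes, left out miRNAs sharing 5 or more bases with the miR-188-5p probe, or used the second slide row alone. What the dmr, hur and mr probes bind is not given in the sources used here. All arrays came from 1 slide. Gene order around Mir188 came from the RefSeq table of GRCm38.p6, without coordinates. The R packages data.table (version 1.17.8) and jsonlite (2.0.0) read the files, and sequence tests and figures used numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.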

Results

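MicroRNAs (miRNAs, short RNAs that repress messenger RNAs) were measured in bone marrow stromal cells of female C57BL/6 mice, cells that can form osteoblasts or adipocytes. The cells had been sorted as positive for CD29 and Sca-1 and negative for CD45 and CD11b, which are surface proteins of white blood cells. They came from 3 aged mice of 18 months and 3 young mice of 3 months, with 1 single-colour array per mouse, so that n = 3 in each group throughout and the number of arrays limits the precision. Of 1247 mouse miRNAs on the array, 365.7 ± 8.50 (SD, n = 3) were detected in aged and 279.0 ± 3.61 (SD, n = 3) in young samples (exact two-sided permutation p = 0.1, the smallest 3 against 3 allow). No spot carried a saturation mark on any array. Over the 221 miRNAs detected on all 6 arrays, Pearson's r across miRNAs, which are not independent replicates, was 0.991 to 0.995 between aged arrays, 0.997 between young arrays and 0.567 to 0.634 between an aged and a young array.

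The first comparison asked whether miR-188, which the series title names, differed between aged and young cells. Both arms of the miR-188 hairpin were higher in aged cells. miR-188-5p had a log2 scaled signal of 11.31, 11.30 and 11.46 in aged samples 1 to 3 and of 6.06, 4.59 and 6.02 in young samples 1 to 3, where 0 is the array's 75th percentile. The group means were 11.36 ± 0.09 (SD, n = 3) and 5.55 ± 0.84 (SD, n = 3). Their difference was 5.80 (moderated SE of limma 0.32) or 55.8-fold (limma adjusted p = 5.15e-09). This size depended on the processing, with a log2 change of 3.99 with quantile normalization, 4.17 with the brightest probe alone, 4.45 with the 75th percentile over all miRNAs, 5.13 with the median, 5.20 in the series matrix and 7.31 with arrays scaled to the control probes named hur and mr, past the threshold in each. miR-188-3p had a log2 scaled signal of 6.89, 7.50 and 6.61 in aged samples and was not detected on any young array, so that it was at least 9630-fold higher in aged cells (limma adjusted p = 1.77e-13). That bound, 13.23 on the log2 scale, holds for the scaling and floor used. The fitted log2 change of miR-188-3p was 12.57 with a higher floor and 12.60 with quantile normalization. It was 12.63 with the 75th percentile over all miRNAs and 16.66 in the series matrix. With normexp background correction, whose offset of 50 compresses dim signals, it was 8.22. The exact two-sided permutation test gave p = 0.1 for each arm, the smallest that 3 against 3 samples allow.

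miR-188-5p made up 75.3%, 71.9% and 75.1% of the summed miRNA signal in aged samples 1 to 3, against 11.3%, 4.75% and 11.8% in young samples 1 to 3. The summed signal itself was 2343005 ± 98820 (SD, n = 3) in aged and 324442 ± 3794 (SD, n = 3) in young samples. The 4 probes of miR-188-5p did not give the same fold. The probe that was dimmest in young cells went from an unscaled signal of 677 ± 320 (SD, n = 3) to 406041 ± 18865 (SD, n = 3). After scaling, the difference of mean log2 values was 592-fold for this probe and 365-fold, 87.7-fold and 18.9-fold for the others. On the aged arrays the brightest probe was 1.11 to 1.13 times as bright as the dimmest, and on the young arrays 30.1 to 39.6 times.

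**Figure D1:**
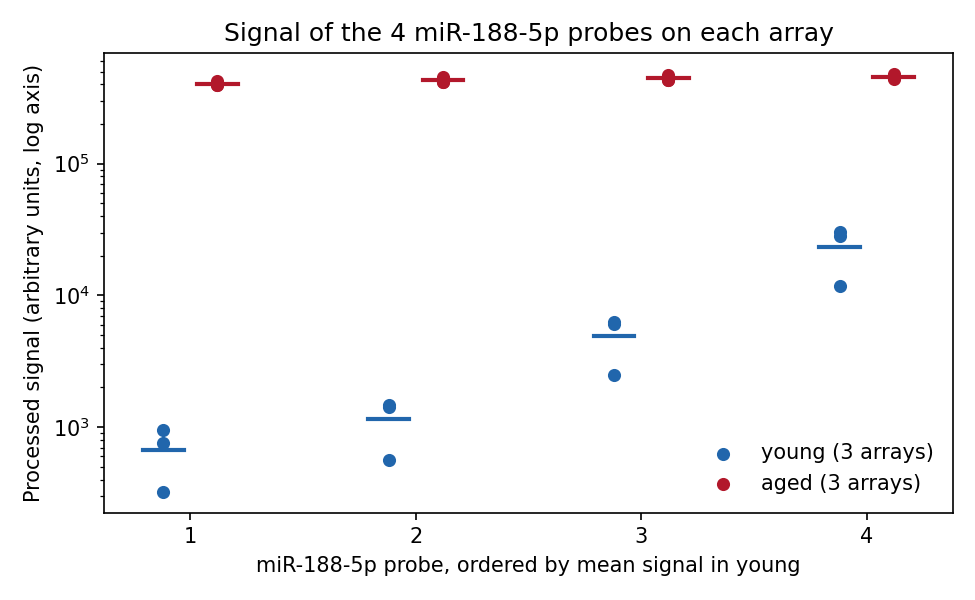
Processed signal (log axis, arbitrary units) of each of the 4 miR-188-5p probes, in order of their mean in young cells, with 1 point per array and a line at the mean of the 3 arrays. All 4 probes sit between 393200 and 480500 on the aged arrays, while the means on the young arrays run from 677 to 23485.

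The authors' deposited table places miR-188 on chromosome X. In the RefSeq annotation of the mouse assembly GRCm38.p6, its gene lies within Clcn5, a chloride transporter gene, with Mir500, Mir501 and Mir362 on one side and Mir532 on the other. Of 10 listed arms of this cluster on the array, 6 could be tested, and next to the 2 arms of miR-188 the other 4 were lower in aged cells (limma adjusted p from 3.34e-07 to 0.0023). miR-500-3p had a log2 change of -0.55, miR-532-5p of -1.46, miR-362-5p of -1.55 and miR-362-3p of -2.02. With arrays scaled to the hur and mr control probes, miR-500-3p and miR-532-5p turned to 0.95 and 0.05, while miR-362-5p stood at -0.26 and miR-362-3p at -0.52. The miR-362 arms were not detected on any aged array and were at least 1.79-fold (miR-362-5p) and at least 3.25-fold (miR-362-3p) lower. The cluster's median was -1.003 and its mean 2.31, and the gene set test camera gave down (adjusted p = 0.457) where fry gave up.

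Across all miRNAs, aged and young cells differed widely. Of 393 miRNAs tested, 207 were higher and 164 were lower in aged cells (55.8% of the calls higher), and 22 did not pass. Of those higher, 115 were not detected on any young array, and of those lower, 35 were not detected on any aged array. Within the 221 miRNAs detected on all 6 arrays, 81 rose and 120 fell. The control probes of the arrays differed too. The 5 bright probes named hur and mr were 2.55-fold brighter on the young arrays (log2 change before scaling -1.35, SD 0.10 in aged and 0.11 in young, n = 3), and the 4 bright dmr probes 1.13-fold brighter (exact two-sided permutation p = 0.1 for each set). The control named miRNABrightCorner30 was also brighter on the young arrays, at 1378 ± 198 (SD, n = 3) against 376 ± 95.5 (SD, n = 3) on the aged ones. With arrays scaled to the hur and mr probes, a choice made after seeing the data, 285 miRNAs were higher and 39 lower, or 88.0% higher. Lower calls were in the majority with the 75th percentile over all miRNAs (174 higher, 204 lower), quantile normalization (175 and 198), the series matrix values (176 and 193) and normexp background correction (161 and 169). The median log2 change over the miRNAs tested was 0.80, ran from -0.56 to 1.14 over the other scalings and was 2.31 with the hur and mr probes, so that each change given here is relative to the 75th percentile of the array unless said otherwise.

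The 12 rises named by their fitted change, in which values at the floor have no order, included both arms of miR-142, which is abundant in blood cells, miR-184-3p, known from the cornea and lens, and miR-486-3p, from a hairpin of red blood cells and muscle. Apart from miR-188-3p, those not detected in young cells were miR-342-5p (at least 10034-fold higher), miR-142-5p (at least 1183-fold), miR-181a-1-3p (at least 804-fold), miR-184-3p (at least 8.95 on the log2 scale), miR-876-3p (at least 196-fold), miR-127-5p (at least 183-fold), miR-142-3p (at least 175-fold), miR-486-3p (at least 143-fold) and miR-770-3p (at least 131-fold). Their limma adjusted p ran from 5.52e-15 to 6.26e-12. All of their young values stood at the floor, with an SD of 0, so that these p-values do not measure spread between young samples. The same holds for miR-188-3p. miR-3072-5p and miR-6349 were detected in both groups. miR-3072-5p went from -1.68 ± 0.12 (SD, n = 3) in young to 7.02 ± 0.29 (SD, n = 3) in aged cells, a log2 change of 8.69 (SE 0.16) or 414-fold, and miR-6349 from -5.47 ± 0.20 to 2.58 ± 0.33 (SD, n = 3), a log2 change of 8.06 (SE 0.18) or 266-fold. Next among rises measured in both groups was miR-6368, outside the 12 and 151-fold higher, which exceeds the bounds of miR-486-3p and miR-770-3p. The miR-6368 probe shares a stretch of 8 bases with the miR-188-5p probe, and those of miR-3072-5p, miR-6349 and miR-770-3p share 6. Their folds may thus carry signal of miR-188-5p, which was not tested one by one. miR-127-5p shares 5 bases, and the remaining rises named here, apart from miR-188-3p, share 2 to 4. With the total signal per miRNA that the scanner software gives, miR-6349 turned to -2.07, though not with the software's totals per probe summed.

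The largest fall measured in both groups was that of miR-3473b, which went from 3.73 ± 0.25 (SD, n = 3) in young to -1.72 ± 0.02 (SD, n = 3) in aged cells and was 43.7-fold lower (limma adjusted p = 1.33e-11). miR-5128 was 25.2-fold, miR-3096a-5p 20.5-fold, miR-690 15.1-fold and miR-494-3p, of the imprinted Dlk1-Dio3 region, 7.09-fold lower, with miR-690 detected on 2 of the 3 aged arrays. With the scanner software's totals per miRNA miR-5128 turned to 4.29, though not with its totals per probe summed. The other 7 of the 12 falls named by their fitted change were not detected in aged cells: miR-714 was at least 18.7-fold lower, miR-3473a at least 14.9-fold, miR-878-3p at least 8.10-fold, miR-6354 at least 6.70-fold, miR-3473e at least 5.64-fold, miR-681 at least 4.16-fold and miR-6418-5p at least 3.98-fold. Falls measured in both groups and outside the 12, such as miR-30b-5p (6.95-fold) and miR-3096b-5p (6.16-fold), exceed some of these bounds. Members of the miR-3473 and miR-3096 families have related sequences and their probes can share signal, so that changes of single members are uncertain. Not all went down, since miR-3473c was higher in aged cells, with a log2 change of 4.59.

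**Figure D2:**
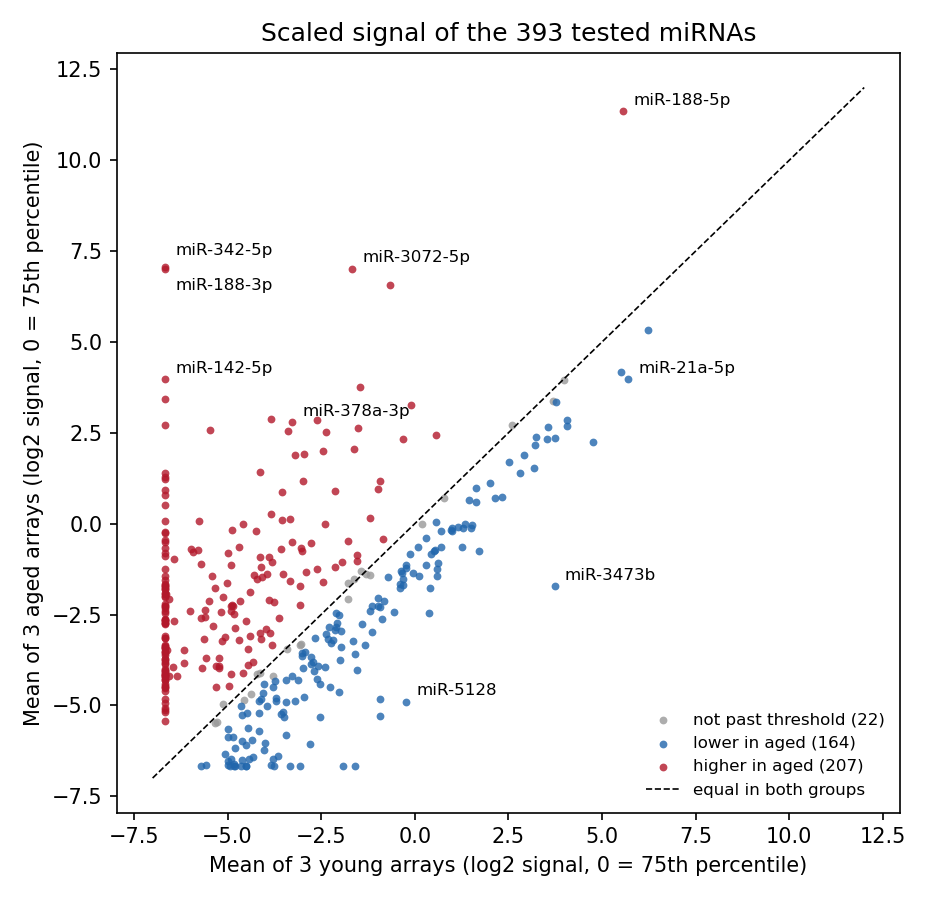
Mean log2 scaled signal of the 3 aged arrays against that of the 3 young arrays for the 393 tested miRNAs, coloured by the limma call, with a dashed line of equal signal; 0 is the array's 75th percentile and points at the left and lower edge are at the floor of -6.66. The 164 lower miRNAs, of which 39 stay lower with arrays scaled to the hur and mr probes, lie mostly in a band below the line, while the 207 higher ones spread far above it.

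By mean log2 signal over all 6 samples, which pools aged and young levels, the 5 brightest miRNAs were miR-188-5p, miR-6366, miR-5109, miR-21a-5p and miR-5126. miR-21a-5p, abundant in fibroblastic cells, went from 5.69 ± 0.07 (SD, n = 3) in young to 3.97 ± 0.14 (SD, n = 3) in aged cells, a log2 change of -1.71 (SE 0.14) that was -0.21 and no longer passed with the hur and mr scaling. miR-5109 had a log2 change of -1.34 and miR-6366 of -0.90, which turned to 0.17 and 0.60 with that scaling. miR-5126 stood at 3.98 ± 0.08 (SD, n = 3) in young and 3.95 ± 0.09 (SD, n = 3) in aged cells, did not pass the test (limma adjusted p = 0.830) and had a log2 change of 1.48 with that scaling.

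Lists of miRNAs fixed by cell type before the data were examined moved apart. Of 19 tested miRNAs abundant in mesenchymal cells, 17 fell and 1 rose, with a median log2 change of -1.19 that turned to 0.32 with the hur and mr scaling. Against the other miRNAs the list was down (camera adjusted p = 6.42e-04; adjusted p = 0.495 with an estimated correlation). miR-23a-3p had a log2 change of -2.46, miR-23b-3p of -1.84, miR-21a-5p of -1.71 and miR-22-3p of -1.64, miR-152-3p was the exception at 1.34, and miR-100-5p at -0.08 did not pass. All 6 tested miRNAs of white blood cells rose, with a median of 4.63, also with undetected members at their bound (camera adjusted p = 0.036; adjusted p = 0.495 with an estimated correlation). The list did not pass camera with the dmr (adjusted p = 0.0504) or the hur and mr scaling (adjusted p = 0.096). Of these, miR-142-5p and miR-142-3p have the bounds given above, and miR-342-3p was 37.5-fold and miR-155-5p 16.4-fold higher. The rises of miR-223-3p and miR-181a-5p were smaller, with log2 changes of 1.96 and 1.31. A further 2 listed members, miR-150-5p and miR-146a-5p, were not detected on any array. Of the 6 tested, 3 were undetected on all young arrays and passed the filter through the aged arrays alone. Members of that kind could hardly fall, so that the filter in part sets the list's count and median.

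All 5 tested muscle miRNAs rose, with a median of 4.04, or 3.62 at the bound (camera adjusted p = 0.065, not past). miR-133b-3p was at least 63.5-fold, miR-133a-3p at least 18.0-fold, miR-1a-3p at least 12.3-fold and miR-499-5p at least 2.66-fold higher. Of 10 listed epithelial miRNAs on the array, 3 could be tested. All 3 rose, with a median of 3.57 (camera adjusted p = 0.147, not past). miR-141-3p was at least 19.5-fold, miR-183-5p 11.9-fold and miR-200b-3p at least 5.64-fold higher. miR-451a, an abundant miRNA of red blood cells, was the sole tested member of its list and was at least 32.7-fold higher. Neither arm of the endothelial miR-126 was detected on any array. Of 39 listed miRNAs of the imprinted Dlk1-Dio3 region on the array, 10 could be tested. Of these, 9 rose and 1 fell, with a median of 3.34, or 2.95 at the bound (camera adjusted p = 0.052, not past). miR-770-3p was at least 131-fold, miR-409-3p at least 27.5-fold, miR-134-5p 17.3-fold and miR-666-5p at least 8.48-fold higher, and miR-494-3p was the exception. Undetected on all young arrays were 4 of the 5 muscle, 2 of the 3 epithelial and 7 of the 10 Dlk1-Dio3 miRNAs. They passed the filter through the aged arrays alone and could hardly fall, so that the filter in part sets the counts and medians of these lists.

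The lists tied to the osteoblast and adipocyte fates were mixed, and none of the 4 passed camera. Of 5 tested miRNAs reported to target Runx2, the master transcription factor of osteoblasts, 4 fell and 1 rose, with a median of -1.36 that turned to 0.14 with the hur and mr scaling (camera adjusted p = 0.149). miR-23a-3p had a log2 change of -2.46, miR-30c-5p of -1.99 and miR-34c-5p of -1.36, and miR-133a-3p, also in the muscle list, rose. Of 9 tested miRNAs reported to favour osteoblasts, 2 rose, 4 fell and 3 did not pass, with a median of -0.21 that was 0.13 with the dmr and 1.30 with the hur and mr scaling (camera adjusted p = 0.343). miR-196a-5p was at least 6.22-fold higher, and miR-20a-5p, miR-22-3p and miR-29b-3p had log2 changes of -2.04, -1.64 and -0.92.

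Of 10 tested miRNAs reported to favour adipocytes, 4 rose, 5 fell and 1 did not pass. miR-375-3p was at least 79.1-fold, miR-378a-3p 66.9-fold, miR-148a-3p at least 22.9-fold and miR-107-3p 6.26-fold higher. The median was -0.28, or 0.06 with the dmr and 1.23 with the hur and mr scaling, the mean 1.46, camera gave down (adjusted p = 0.747) and fry up. Of 9 tested miRNAs reported to hold back adipocytes, 3 rose and 6 fell. miR-130b-3p was at least 107-fold, miR-155-5p, also in the list of white blood cells, 16.4-fold and miR-448-3p at least 4.71-fold higher, and miR-221-3p had a log2 change of -1.36. The median was -1.08, or 0.42 with the hur and mr scaling, the mean 0.76, camera gave down (adjusted p = 0.343) and fry up.

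By their medians, the groups tied to senescence and proliferation were lower relative to the 75th percentile and not relative to the hur and mr probes. All 10 tested senescence miRNAs fell, with a median of -1.49 (-1.38 at the bound) that turned to 0.02 with the hur and mr scaling (camera adjusted p = 0.0039; adjusted p = 0.495 with an estimated correlation). They included the p53-induced miR-34a-5p at -1.90 and miR-34b-5p at -1.62, besides miR-21a-5p and miR-22-3p. Of 9 let-7 miRNAs, which hold back proliferation, 8 fell, with a median of -0.85 that turned to 0.65 with that scaling (camera adjusted p = 0.024; adjusted p = 0.495 with an estimated correlation). let-7g-5p had a log2 change of -1.42, let-7i-5p of -1.21, let-7f-5p of -1.04 and let-7d-5p of -0.91. These 9 are the preset members of the list. Other let-7 miRNAs tested outside it rose: let-7k (4.40), let-7f-1-3p (2.63) and let-7b-3p (2.57). Of 10 tested miRNAs of the growth-promoting miR-17 clusters, 8 fell and 2 rose, with a median of -1.25 that turned to 0.26 (camera adjusted p = 0.0498; adjusted p = 0.495 with an estimated correlation). miR-20a-5p had a log2 change of -2.04, miR-19b-3p of -1.71 and miR-92a-3p of -1.45, whereas miR-363-3p was at least 20.1-fold higher. This list takes a single preset arm of each hairpin. Arms of these clusters outside it rose: miR-17-3p (5.85), miR-18b-3p (3.11) and miR-18a-3p (2.69).

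Of 8 miR-29 and miR-30 miRNAs, which repress collagens (miR-29) among other targets, 7 fell, with a median of -1.12 that turned to 0.38 with the hur and mr scaling (camera adjusted p = 0.024; adjusted p = 0.495 with an estimated correlation). miR-30b-5p had a log2 change of -2.80, miR-30c-5p of -1.99, miR-30a-5p of -1.57 and miR-30e-5p of -1.33. Among tested arms outside this list, miR-29b-2-5p (2.40) and miR-30a-3p (1.77) rose, while miR-29b-1-5p (-0.72) and miR-30c-2-3p (-1.37) fell. miR-30c-1-3p and miR-30e-3p did not pass. With the scanner software's totals per miRNA miR-30b-5p turned to 2.02 and miR-30c-5p to 1.01, and neither turned with its totals per probe summed. Of 17 tested members of the repeat-rich miR-466, miR-467, miR-669 and miR-297 families, 15 fell, with a median of -0.997 (-0.88 at the bound) that turned to 0.51 with the hur and mr scaling (camera adjusted p = 0.0028; adjusted p = 0.495 with an estimated correlation). miR-467b-5p had a log2 change of -1.67 and miR-467a-3p of -1.35. With the totals per miRNA miR-467b-5p turned to 0.97, though not with the totals per probe summed. miR-467e-5p and miR-467a-5p, not detected in aged cells, were at least 2.13-fold and at least 1.70-fold lower. These copies are near-identical, so that single members are uncertain. Of 17 tested GC-rich miRNAs that are often bright on arrays, 6 rose and 8 fell. Their median was -0.21, or 0.13 with the dmr and 1.30 with the hur and mr scaling, the mean 1.09, camera gave down (adjusted p = 0.538) and fry up. miR-3072-5p, miR-188-5p, miR-1894-3p (34.3-fold higher) and miR-134-5p had the largest rises in this list.

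**Figure D3:**
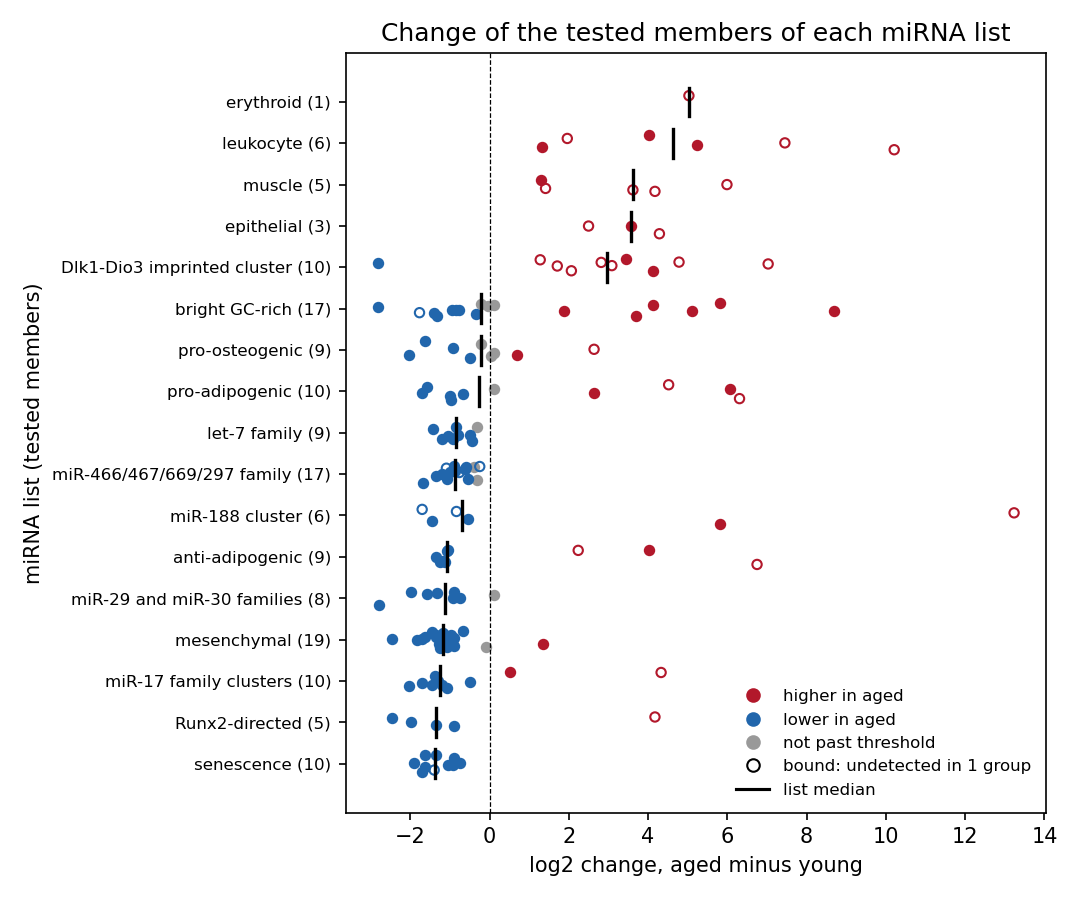
Log2 change (aged minus young) of each tested member of the miRNA lists, with open circles at the bound for members undetected in 1 group and a black bar at the list's median computed in the same way. The leukocyte, muscle, epithelial and Dlk1-Dio3 medians lie between 2.95 and 4.63, and the senescence, mesenchymal and miR-17 medians between -1.38 and -1.19, though above 0 with arrays scaled to the hur and mr probes.

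In all, camera with a preset correlation of 0.01 passed 7 of 16 lists, 1 up and 6 down, and with an estimated correlation 0 of 16. fry, which does not compare a list with other miRNAs, passed all 16. With the dmr scaling the let-7 and miR-17 lists did not pass camera (adjusted p = 0.0504 for each), nor with the hur and mr scaling these (0.353 and 0.168), the miR-29 with miR-30 (0.096) and the miR-466 to miR-297 list (0.115). Counts adjusted over the list alone equalled those adjusted over all miRNAs tested in each list, except for 7 in place of 8 falls in the GC-rich list. The arrays lay in 2 rows of 1 slide, with aged samples 1 and 2 alone in the first row. With the row as a block 361 miRNAs and 5 lists passed. Within the second row, where the lone aged sample 3 is assumed to vary like the 3 young samples, 349 miRNAs and 7 lists passed. By the design both fits set aged sample 3 against the young samples, a log2 change of 5.91 for miR-188-5p.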

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

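The dmr, hur and mr scalings, the summed probe totals, the set without probes sharing 5 or more bases and the second slide row alone were chosen after seeing the data. miR-188-5p kept its direction and passed under all 27 alternatives (3.99 to 7.31), as did miR-188-3p under 26 (8.22 to 16.66). Of the other comparisons of named miRNAs with an alternative, 1914 kept direction and call, 15 lost the call, 2 gained it and 20 turned. Of those of lists, 385 kept it, 32 lost it and 13 gained it. Of the 7 lists that passed, mesenchymal kept its call under 27 of 27 alternatives, senescence under 26, miR-466 to miR-297 under 25, miR-29 with miR-30 under 24, leukocyte under 22, let-7 under 19 and miR-17 under 14, all at the preset correlation, while none of the 7 passed with an estimated correlation (adjusted p = 0.495 for each). With the scanner software's total per miRNA, 4 lists passed and the correlation between replicates was 0.953, and miR-6349 (-2.07), miR-5128 (4.29), miR-30c-5p (1.01), miR-30b-5p (2.02) and miR-467b-5p (0.97) turned. That total exceeded 1.5 times the sum over the miRNA's own probes for 70 to 84 detected miRNAs per array. On the array of aged sample 1, for example, miR-6373 carried a total of 20460 with a probe sum of 8.77, close to the total of 20456 of miR-6368. With the software's totals per probe summed, 366 calls were kept and 0 turned, so these turns came from the total per miRNA. With miRNAs detected on all 6 arrays, 221 in number, 204 changed, 81 were higher and 1 list passed. With the dmr scaling 4 lists passed. With the hur and mr scaling 39 miRNAs were lower, 2 lists passed, and these turned: miR-6366 (0.60), miR-5109 (0.17), miR-5126 (1.48), miR-34c-5p (0.14), miR-29b-3p (0.59), miR-221-3p (0.14), let-7g-5p (0.088), let-7i-5p (0.29), let-7f-5p (0.46), let-7d-5p (0.59), miR-92a-3p (0.055), miR-30e-5p (0.17), miR-467e-5p (0.14), miR-467a-3p (0.16) and miR-467a-5p (0.22). The causes of the other shifts were not tested. The filter left fewer miRNAs to test and also moved the median change over the miRNAs tested from 0.80 to -0.60. camera sets a list against those miRNAs, so that the loss of lists is not put down to their number alone. Leaving out 1 replicate gave 363 to 374 changed miRNAs, 205 to 206 higher, 158 to 168 lower, 6 to 9 lists, and 5.32 to 6.05 for miR-188-5p and 13.41 to 13.85 for miR-188-3p. With the replicate number as a block, 369 miRNAs (207 higher, 162 lower) and 5 lists passed, without let-7 (adjusted p = 0.087) and miR-17 (0.096). Same-numbered samples correlated at -0.29, -0.11 and -0.14 in their deviations from the group means, and so were no more alike than other pairs. Deviations within groups of 3 are tied to one another, so that these values do not exclude a pairing. The authors' standardized table was not run because its columns match no label, nor a slide or scan block because there was 1 of each. Signal over background limits the 115 rises and 35 falls undetected in 1 group to bounds.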

Other observations

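The tests of explanations below, the count of splits for lists and the dmr and the hur and mr scalings were chosen after the result was seen, whereas the count of splits for changed miRNAs, the other scalings, the brightest probe and the slide row as a block were planned. Both arms of 53 hairpins were tested, and both passed in 47. They moved the same way in 35 (24 higher, 11 lower), where 25.1 would do so if arms were independent, and opposite ways in 12. miR-378a-3p, from a hairpin within the metabolic gene Ppargc1b, rose by 6.06 on the log2 scale while miR-378a-5p stood at -0.66, and miR-193b-5p rose by 5.06 while miR-193b-3p stood at -1.27. Related sequences also parted: miR-103-3p stood at -1.01 and miR-107-3p at 2.65, miR-130a-3p at -1.13 with miR-130b-3p at least 107-fold higher, and miR-20a-5p at -2.04 with miR-20b-5p at 0.53, pairs picked after their values were seen. The negative values are relative to the 75th percentile, and the median of all lower calls turned from -1.34 to 0.16 with the hur and mr scaling.

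The number of changed miRNAs was 371 in the real grouping and 0 in each other split of the 6 arrays into 3 and 3 (limma, also 0 at an unadjusted p under 0.05), so that 1 of 10 splits gave as many. Every other split mixes aged and young arrays in both of its groups, so that a large difference by age enters the spread within groups. The miRNAs tested were also chosen by the real grouping. Counts of 0 in the other splits were therefore to be foreseen and decide nothing on chance. For lists, 3 of 10 splits gave as many as the real 7, the highest other giving 8. Each other split passed between 1 and 8 lists, so that the number of lists does not set the real grouping apart. Splits that parted aged samples 1 and 2 still passed 1 to 6. The splits with 8 put aged samples 1 and 2, alone in the first slide row, with young sample 1 or 2, and with the row as a block 5 lists passed. For both counts 10 splits are too few for a share under 0.05.

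The rise of miR-188-5p and miR-188-3p stood against 3 explanations. Scaling between arrays as the whole cause is argued against, since miR-188-5p was 6.14 higher (SE 0.31) with the dmr scaling and at least 3.99 higher with each other scaling tried. A joint rise of its X-linked cluster is argued against by the neighbours' median of -1.50, which was -0.11 with the hur and mr scaling, though miR-500-3p then passed at 0.95. The 4 probes differed by at most 1.13-fold on an aged array and by 30.1-fold or more on young ones. Probes near the limit of their binding capacity would give this pattern, so that the 55.8-fold may understate the change. The brightest probe alone gave a log2 change of 4.17, but it had the smallest fold of the 4, which such a limit would also give. Quantile normalization gave 3.99, so that the size also depends on the scaling. Age itself stays open, untested, and so does any difference in how the aged samples were prepared.

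The 207 miRNAs called higher may in part carry signal of miR-188-5p on other probes. The rank correlation of log2 change with the stretch shared with the miR-188-5p probe (CCCTCCACCATGC) was 0.12 with GC content taken out, higher than for 95.3% of 1245 other probes used in its place, narrowly past the 95% set, with 59 others as high and the highest at 0.24. The relation was not steady, with medians of 2.14 for the 42 miRNAs sharing 2 bases, -0.66 for 146 sharing 3, 0.28 for 110 sharing 4 and 2.70 for 93 sharing 5 or more. As the whole cause such signal is argued against, since 42.9% of the 205 higher calls other than the miR-188 arms share 3 bases or fewer. After a linear trend on GC content was taken out, the median of the higher calls was 2.62, against 3.05 before. Since these miRNAs were picked for their rise, that median alone does not decide on GC content. The rank correlation of change with GC content was 0.19 over all 391 miRNAs. So low a value argues against a steady GC trend as the whole cause. RNA of other cells stays open, with 6 of 8 listed leukocyte miRNAs higher despite the sort against CD45. Of these 6, 3 were undetected on all young arrays and were tested only through their aged signal. Age stays open, untested.

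Of the 164 miRNAs called lower, 120 were detected on all arrays, and 74.2% of these lay within 1.5-fold of their median of -1.21, with a range from -5.45 (miR-3473b) to -0.34, against 27.2% of the 81 higher ones around theirs. Before scaling, the median of the 120 was -1.06, and the dmr probes changed by -0.18 (SE 0.11), which argues against labelling or hybridisation as read by these probes as the whole cause. The control miRNABrightCorner30, at 1378 on the young and 376 on the aged arrays, goes the other way. Labelling or hybridisation outside what the dmr probes read therefore stays open. The hur and mr probes changed by -1.35 (SE 0.086), which is large enough for a lower yield of an RNA fraction that they and the lower miRNAs share. What the probes bind is not given in the sources used here, and scaling to them moves each of the 120 miRNAs by a single amount (1.505 on the log2 scale), so that how many of these turn cannot test that explanation, which stays open. Age stays open, untested.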
